A study of Mus musculus with 11 samples.

How the data were processed

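Thymic epithelial cells of NOD mice aged 4 to 8 weeks were profiled by RNA sequencing in 11 libraries, 3 WT/WT, 5 WT/R249C and 3 R249C/R249C for Aire. Per the labels, CD45-positive cells were depleted with magnetic beads, EpCAM-positive and CD45-negative cells were sorted, and libraries were made from low-input RNA. The deposited table holds whole-number counts per gene and library, not normalized. Per the submitters' processing notes, FastQC, HISAT2 and StringTie were run against mouse build mm39, without versions; whether the counts were tallied reads or were derived from StringTie coverage is not given in the sources used here, nor is the annotation release. The column names of the 7 libraries of batch A carry the word trimmed and those of the 4 libraries of batch B do not, so trimming may differ between the batches.

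Batch A holds 1 WT/WT, 3 WT/R249C and 3 R249C/R249C libraries, and batch B holds 2 WT/WT and 2 WT/R249C libraries. For WT/R249C replicates 4 and 5 the labels contradict each other: the title and the library name read WT/R249C and the genotype field reads R249C/R249C. They were grouped by title, and 2 alternatives left them out or counted them as R249C/R249C. They are the only WT/R249C libraries of batch B, so every WT/R249C value given within batch B rests on them. Without them every mutant library is in batch A, so a fit with a batch term compares both mutant genotypes with WT/WT replicate 1 alone. The titles call the libraries biological replicates. Nothing says how many mice each library pools, so the p-values measure the spread between libraries. The labels also hold a library number, which differs from the replicate number of the title for WT/WT. By library number WT/WT replicates 1, 2 and 3 match WT/R249C replicates 3, 4 and 5. The replicate block used the replicate number of the title.

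Ensembl identifiers were matched to symbols through GENCODE names of an older release, used for names only: 52073 of the 56691 genes in the table had a symbol, and at least 99.7% of the counts of every library fell on them. Library totals ran from 60560348 to 182319976 counts. Reads carry no molecular identifiers, so floors cover counting error only, while the intervals of fold changes come from the edgeR fit and reflect the spread between libraries. A fold against a group whose libraries were all at 0 is given as a lower bound against a floor of 3 counts over the group. The 55 pairwise correlations of log CPM (counts scaled to a common library total) ran from 0.738 to 0.888, with a median of 0.814 within and 0.816 between groups.

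Differences were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM scaling, low counts removed with filterByExpr), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. WT/WT was compared with each mutant genotype in a single fit of all 11 libraries with batch as a term, so fitted log2 fold changes are batch-adjusted while CPM means are not. R249C/R249C was compared with WT/R249C in the 6 batch A libraries. Intervals of fold changes are at 95%. DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights) were run beside it. Gene lists fixed beforehand, 36 in all and matched for 498 of 501 entries, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The fry PValue tests whether a list's genes move, on balance, one way, and PValue.Mixed whether they change in either direction; neither compares the list with other genes.

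Genes with at least 1 count were tallied per library after thinning to the smallest total, as the mean of 10 draws. A tissue-gene score was the mean log2(CPM + 1) of 196 tissue-restricted genes. Both were compared by exact permutation of the group labels, two-sided, where 3 against 3 libraries allow no p below 0.1 and 3 against 5 none below 0.0179.

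The named genes are, by a rule fixed before the data were examined, Aire, the 10 genes of smallest adjusted p per direction or, where none passed, the 5 of smallest raw p per direction, and up to 4 list members of smallest raw p. Gene models with a Gm number, a Rik name or a bare ENSMUSG, MSTRG or LOC identifier, Xist and Y-linked genes were left out of the naming. The text takes up to 2 of the first members of the lists it discusses, a restriction set after the lists had been tested.

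The design, the tests, the lists and most alternatives (scaling, filters, DESeq2, replicate block, batch, contested labels, leaving out each library) were also set then. Limma voom, a filter at a mean CPM of 10, a covariate for mature medullary markers, leaving out the sparsest WT/R249C libraries and the summed immunoglobulin genes were added after seeing the data.

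The edgeR fit was tested on simulated data of the same group sizes, drawn from a negative binomial model at the fitted dispersions and without a batch difference. In each run 67 genes were changed 2-fold, 67 changed 4-fold and 66 changed 8-fold together. The shares recovered depend on these numbers. Among genes of at least 10 CPM, it recovered 48.5% of genes changed 8-fold and 19.4% of those changed 4-fold for R249C/R249C against WT/WT, 75.8% and 25.4% for WT/R249C against WT/WT, and 51.5% and 16.4% for R249C/R249C against WT/R249C. Of genes changed 2-fold it recovered 0%, 2.99% and 0%. Among all genes tested, it recovered 19.7%, 31.8% and 15.2% of genes changed 8-fold, 5.97%, 10.4% and 1.49% of those changed 4-fold, and 0% of those changed 2-fold in each comparison.

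Every column of the table was used. Read files were not analysed here, so the R249C change itself was not read from the sequences. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.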

Results

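Aire drives the expression of tissue-restricted genes in mature medullary thymic epithelial cells, which show these proteins to developing T cells. R249C is a missense variant in the SAND domain of Aire, and NOD is a mouse strain prone to autoimmune diabetes. EpCAM-positive, CD45-negative thymic cells were sequenced from 3 WT/WT, 5 WT/R249C and 3 R249C/R249C libraries. Total counts per library were 105630818, 123454878 and 182319976 for WT/WT. They were 142186501, 118504166, 60560348, 129229681 and 83119070 for WT/R249C, and 112404478, 103467438 and 91946272 for R249C/R249C. Values below are CPM (counts scaled to a common library total), mean ± SD over the libraries of a group.

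The Aire transcript was present in every library, at 490 ± 244 CPM in WT/WT (n = 3), 518 ± 228 in WT/R249C (n = 5) and 603 ± 272 in R249C/R249C (n = 3). Single libraries ran from 174 to 858 CPM, and Aire did not differ between genotypes beyond this spread. Its log2 fold change was 0.57 (95% interval -0.95 to 2.09) for R249C/R249C against WT/WT, 0.20 (-1.0 to 1.40) for WT/R249C against WT/WT and 0.26 (-1.21 to 1.72) for R249C/R249C against WT/R249C, each with an edgeR adjusted p of 1. Within batch A the first 2 were 0.96 and 0.69. Within batch B, where the WT/R249C libraries are those with contradicting labels, the second was -0.14. The sign of the second rested on WT/WT replicate 1 (-0.14 without it), and that of the third on WT/R249C replicate 2 (-0.15 without it) and R249C/R249C replicate 3 (-0.05 without it).

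Over all libraries, the mean tissue-gene scores of the genotypes differed by less than the SD of WT/WT. The tissue-gene score was 1.57 ± 0.42 in WT/WT, 1.51 ± 0.34 in WT/R249C and 1.40 ± 0.09 in R249C/R249C. Exact permutation tests, two-sided, gave p = 0.6 for R249C/R249C against WT/WT (n = 3 and 3, smallest possible 0.1), p = 0.804 for WT/R249C against WT/WT (n = 5 and 3, smallest possible 0.0179) and p = 0.643 for R249C/R249C against WT/R249C. Within batch A the same differences were 0.28 (exact p = 0.25, the smallest possible), 0.27 (exact p = 0.75, smallest possible 0.25) and 0.01 (exact p = 1, smallest possible 0.1). The first 2 are against a single WT/WT library, which at 1.12 lay below all 3 R249C/R249C libraries. Without it the difference between R249C/R249C and WT/WT was -0.40 (exact p = 0.1, the smallest possible). R249C/R249C is then all of batch A and WT/WT all of batch B, so genotype cannot be told from batch. An effect on this score is left open. The thinned libraries held 26007 ± 2958 genes in WT/WT, 26158 ± 3543 in WT/R249C and 25890 ± 1250 in R249C/R249C, with exact permutation p of 1, 1 and 0.857 in the same order. Within batch A the differences were 1448, 2252 and -803 genes, with exact p of 0.5, 1 and 0.9.

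**Figure D1:**
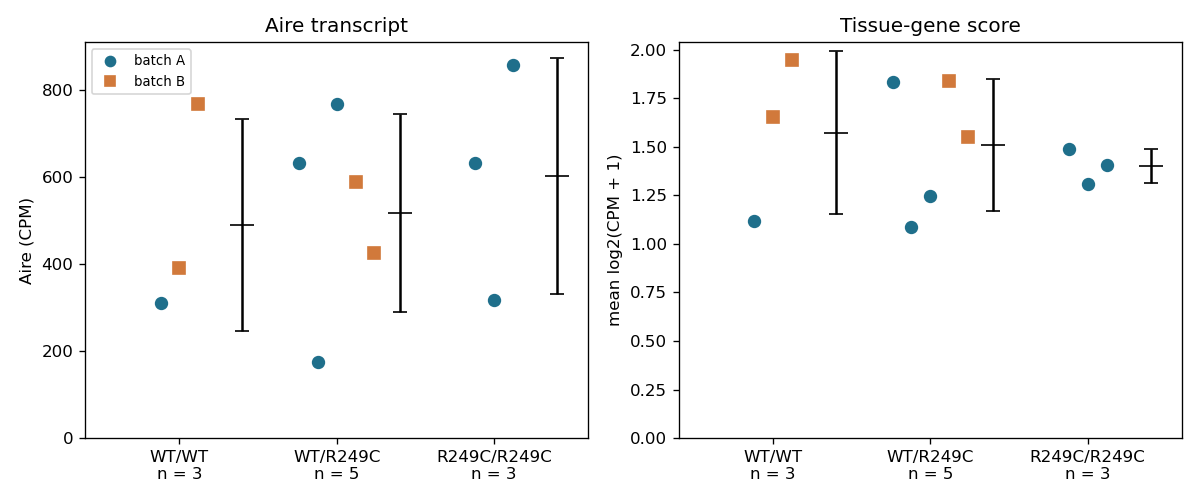
Aire in CPM (left) and the tissue-gene score as mean log2(CPM + 1) (right) for each library, by genotype, with circles for batch A and squares for batch B and black bars for the mean and SD. The genotypes overlap in both measures, with Aire between 174 and 858 CPM.

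The comparison of R249C/R249C with WT/WT asks how thymic epithelial expression differs when both copies of Aire carry the variant. Among the genes with the smallest p were immunoglobulin chains, made by B lineage cells, at lower levels in R249C/R249C. Igkc, the kappa light chain constant region, was at 251 ± 87.7 CPM against 1403 ± 592, Ighg2b, a heavy chain, at 2.14 ± 0.849 against 68.5 ± 29.6, and Igkj5, a light chain joining segment, at 0.408 ± 0.227 against 10.9 ± 6.07 (n = 3 and 3). None of them passed by edgeR or limma voom: edgeR called 0 of 26980 genes, with 865 at an unadjusted p under 0.05, and limma voom called 0. DESeq2 called 408 (156 higher, 252 lower), with these immunoglobulin genes among them.

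The other genes with the smallest p did not pass by edgeR or limma voom either, while DESeq2 called them. Hnrnpdl, an RNA-binding protein of splicing, was at 124 ± 15.2 against 75.8 ± 16.5 CPM (log2 fold change 1.06). Pdcd11, which acts in ribosome assembly, was at 26.5 ± 2.87 against 13.4 ± 7.34 (1.93), and Ensa, a phosphatase regulator of mitosis, at 59.2 ± 25.1 against 27.1 ± 2.39 (1.27). Hsd3b7, an enzyme of bile acid synthesis that also shapes oxysterol signals, was at 31.1 ± 6.13 against 11.4 ± 3.33 (1.64), and Kdm3a, a histone demethylase, at 71.3 ± 11.2 against 48.2 ± 7.68 (0.94). Ggps1, of isoprenoid synthesis, was at 45.1 ± 5.11 against 77.9 ± 21.6 (-1.18). Ly6g5b, a member of the Ly6 family, was at 0 against 2.55 ± 0.774 CPM, at least 274-fold lower. Within batch A, which has a single WT/WT library, the log2 fold changes were -2.69 for Igkc, 1.11 for Hnrnpdl, 2.42 for Pdcd11, 1.20 for Hsd3b7 and -1.18 for Ggps1.

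Among gene lists, those of thymocytes and B cells were lower in R249C/R249C and those of cortical and mature medullary epithelium higher, by camera at its preset correlation. The thymocyte list had a median log2 fold change of -0.93 (adjusted p = 4.69e-05, and adjusted p = 0.453 with an estimated correlation). The T cell receptor component Cd3g was at 12.9 ± 2.96 against 35.4 ± 14.9 CPM and the kinase Lck at 58.4 ± 17.3 against 90.4 ± 11.3. Of its 17 members 2 were higher in R249C/R249C, named here after their values were seen: Cd4 at 17.7 ± 7.03 against 5.34 ± 2.69 CPM and Zap70 at 6.63 ± 1.74 against 2.87 ± 0.597. The B cell list had a median of -0.91 (adjusted p = 0.00106, and adjusted p = 0.282 with an estimated correlation). Ms4a1, a B cell surface protein, was at 0 against 2.66 ± 2.31 CPM, at least 245-fold lower. The ionocyte list had a median of -1.52 (adjusted p = 0.0137, and adjusted p = 0.282 with an estimated correlation). The regulator Foxi2 was at 0.0652 ± 0.113 against 6.67 ± 7.13 CPM.

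The cortical epithelium list had a median of 0.61 (adjusted p = 4.37e-04, and adjusted p = 0.507 with an estimated correlation). Tbata, a regulator of thymic epithelial growth, was at 641 ± 116 against 509 ± 87.5 CPM and the peptidase Enpep at 34.6 ± 9.79 against 18.9 ± 3.15. The mature medullary list had a median of 0.56 (adjusted p = 0.00361, and adjusted p = 0.9 with an estimated correlation). Without batch adjustment, the mean log2(CPM + 1) of its members other than Aire was 7.34 ± 0.37 against 7.22 ± 0.40, a difference within the SD. The class II chain H2-Aa was at 1974 ± 318 against 1639 ± 331. Its member Ccl22, a chemokine, lay the other way at 20.4 ± 5.48 against 61.7 ± 16.8. The list of genes known to need Aire had a median of 1.04 (adjusted p = 0.0327, and adjusted p = 0.9 with an estimated correlation). Bpifb1, a secreted airway and salivary protein, was at 13.7 ± 10.7 against 9.82 ± 7.79, and the milk protein Csn2 at 78.8 ± 3.31 against 73.6 ± 44.5. The upward median comes from the fit with the batch term, since 10 of its 15 members had a lower mean CPM in R249C/R249C. With no batch term the median was -0.39 (adjusted p = 0.836), and without WT/WT replicate 1, the only WT/WT library of batch A, it was 0.39 (adjusted p = 0.1215).

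The epidermis list had a median of 1.36 (adjusted p = 0.00103, and adjusted p = 0.507 with an estimated correlation). Calml3, a calmodulin-like protein of epithelia, was at 23.4 ± 11.5 against 11.7 ± 7.86 CPM and Casp14, a caspase of skin barrier formation, at 2.93 ± 1.39 against 0, at least 396-fold higher. The keratinocyte list had a median of 0.56 (adjusted p = 0.034, and adjusted p = 0.507 with an estimated correlation). The keratinocyte list no longer passed in 15 of 23 alternatives, with medians from 0.16 to 0.94. The epithelial regulator Grhl1 was at 67.3 ± 8.78 against 53.0 ± 10.8, and the list member Pou2f1 at 43.1 ± 12.2 against 26.1 ± 12.2. The cell cycle list had a median of 0.35 (adjusted p = 0.0339, and adjusted p = 0.913 with an estimated correlation). The kinetochore protein Cenpf was at 27.6 ± 9.17 against 15.5 ± 10.5 and the cyclin Ccnb1 at 30.8 ± 11.8 against 22.8 ± 8.65. In the fit with the batch term 14 of its 18 members were higher and 4 lower. The cell cycle list no longer passed in 12 of 23 alternatives, with medians from 0.023 to 0.95. The myeloid list had a median of 1.28 (adjusted p = 0.04, and adjusted p = 0.9 with an estimated correlation). The antibody receptor Fcgr1 was at 1.15 ± 1.01 against 0 CPM, at least 165-fold higher. Siglech, a receptor of plasmacytoid dendritic cells, was at 0.529 ± 0.917 against 0, with all counts of these groups in R249C/R249C replicate 3. In the fit with the batch term, 10 of the 13 measured myeloid members were higher. Some members had a lower mean CPM in R249C/R249C, such as Cd68 at 6.39 ± 4.96 against 13.6 ± 7.96 and Lyz2 at 129 ± 86.1 against 173 ± 100. The myeloid list no longer passed in 17 of 22 alternatives, with medians from -0.16 to 5.46.

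Of the 36 lists, these 10 passed camera at the preset correlation, 0 passed at an estimated correlation and 0 by the fry PValue, and the B cell list passed by PValue.Mixed (adjusted p = 0.00627). The count of 10 was 2 without WT/WT replicate 1 and 6 without R249C/R249C replicate 3, and 4 lists passed within batch A, of which epidermis, thymocytes and B cells are among the 10. Igkc was the 1 list member that passed when adjusted over the list alone, against 0 over all genes.

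The comparison of WT/R249C with WT/WT asks what a single variant copy of Aire does. Immunoglobulin transcripts were again among the genes with the smallest p: Igkc was at 119 ± 92.0 CPM against 1403 ± 592 (n = 5 and 3, log2 fold change -3.80, SE 0.49), lower in each of the 5 WT/R249C libraries than in any of the 3 WT/WT libraries. Its edgeR adjusted p of 0.815 was the smallest of this comparison and did not pass. Ighg2b was at 3.64 ± 2.90 CPM against 68.5 ± 29.6 (-4.22) and Igkj5 at 0.406 ± 0.189 against 10.9 ± 6.07 (-4.72). edgeR called 0 of 26980 genes, with 940 at an unadjusted p under 0.05, limma voom called 0 (smallest adjusted p = 0.0678), and DESeq2 called 274 (155 higher, 119 lower).

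Plcb2, a phospholipase of taste and tuft cells and of leukocytes, was at 11.7 ± 9.69 against 54.0 ± 25.3 CPM (log2 fold change -1.98), and Lman2l, a cargo receptor of the secretory path, at 50.3 ± 8.06 against 80.1 ± 7.48 (-0.73). Hsd3b7 was at 37.6 ± 12.7 against 11.4 ± 3.33 (1.74), Hnrnpdl at 118 ± 21.1 against 75.8 ± 16.5 (0.78) and Pdcd11 at 25.8 ± 7.99 against 13.4 ± 7.34 (1.38). Psmb4, a proteasome subunit, was at 143 ± 29.6 against 91.5 ± 33.9 (0.89), and Rpl22l1, a ribosomal protein paralog, at 65.4 ± 10.97 against 38.7 ± 13.0 (0.94). These genes did not pass by edgeR or limma voom, while each is among the DESeq2 calls. Within batch A and batch B in turn, the log2 fold changes were -3.56 and -3.98 for Igkc, -2.36 and -1.67 for Plcb2, 1.10 and 2.27 for Hsd3b7, and 0.85 and 0.73 for Hnrnpdl. Batch A holds a single WT/WT library, and the batch B values rest on the WT/R249C libraries with contradicting labels.

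**Figure D2:**
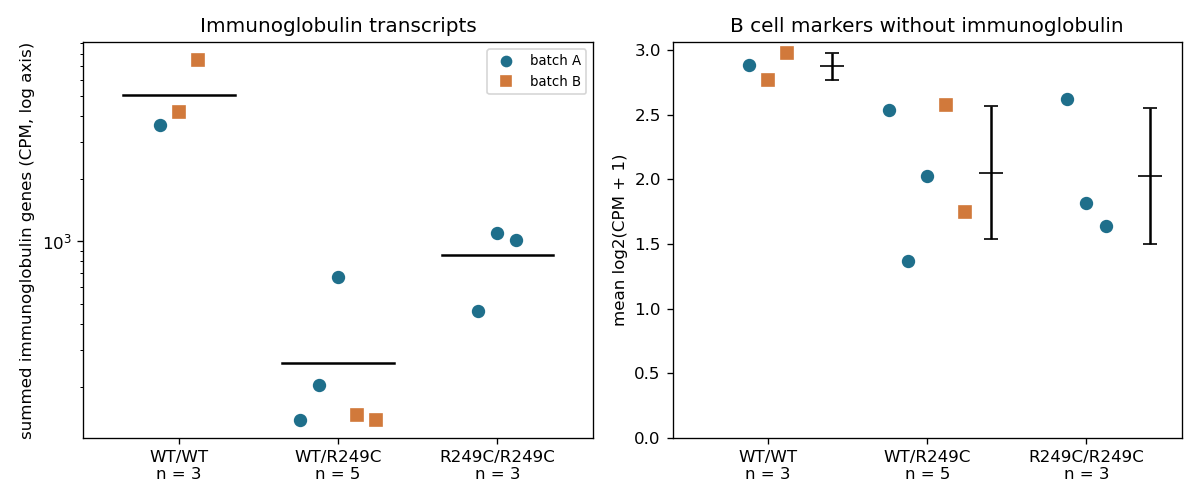
Summed CPM of all immunoglobulin genes on a log axis (left, lines for group means) and the mean log2(CPM + 1) of 8 B cell markers other than immunoglobulin (right, bars for mean and SD) for each library, with circles for batch A and squares for batch B. The 3 WT/WT libraries lie above all 8 mutant libraries in both measures.

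Thymocyte, B cell and fibroblast lists were lower in WT/R249C by camera at its preset correlation. The thymocyte list had a median of -0.99 (adjusted p = 2.15e-07, and adjusted p = 0.346 with an estimated correlation). Cd3g was at 10.8 ± 5.17 against 35.4 ± 14.9 CPM and Lck at 61.0 ± 13.5 against 90.4 ± 11.3. The B cell list had a median of -0.88 (adjusted p = 9.73e-06, and adjusted p = 0.133 with an estimated correlation), with Ms4a1 at 0.364 ± 0.536 against 2.66 ± 2.31. The fibroblast list had a median of -0.82 (adjusted p = 9.73e-06, and adjusted p = 0.398 with an estimated correlation). The collagen Col1a2 was at 28.8 ± 13.9 against 106 ± 33.2 and Col3a1 at 108 ± 49.0 against 340 ± 171. Within batch A the fibroblast list did not pass (median -0.40), and within batch B it did (median -1.44).

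The cortical epithelium list was higher, with a median of 0.60 (adjusted p = 9.73e-06, and adjusted p = 0.398 with an estimated correlation). Enpep was at 34.3 ± 5.67 against 18.9 ± 3.15 CPM and the keratin Krt8 at 1088 ± 273 against 744 ± 341. The interferon list had a median of 0.28 (adjusted p = 0.0135, and adjusted p = 0.873 with an estimated correlation). The antiviral protein Mx1 was at 21.8 ± 10.6 against 12.4 ± 3.94 and the chemokine Cxcl10 at 161 ± 65.3 against 104 ± 33.4. Both lists passed within batch B and neither within batch A, while neither of these 2 interferon genes passed in either batch. The list of genes that need Aire did not pass (median 0.93, adjusted p = 0.182), with Csn2 at 124 ± 89.0 against 73.6 ± 44.5 and the urinary protein Mup20 at 0.836 ± 0.888 against 0.163 ± 0.282. The mature medullary list did not pass either (median 0.20, adjusted p = 0.184), with the class II chain H2-Eb1 at 1211 ± 450 against 795 ± 255 and Ccl22 at 35.0 ± 15.0 against 61.7 ± 16.8.

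Of the 36 lists, these 5 passed camera at the preset correlation, 0 passed at an estimated correlation and 0 by the fry PValue, and the B cell list passed by PValue.Mixed (adjusted p = 3.41e-06). The count of 5 was 8 without WT/WT replicate 2 and 10 without WT/R249C replicate 5. Plcb2, Cd3g and Igkc passed when adjusted over the list alone, 3 genes against 0 over all genes.

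**Figure D3:**
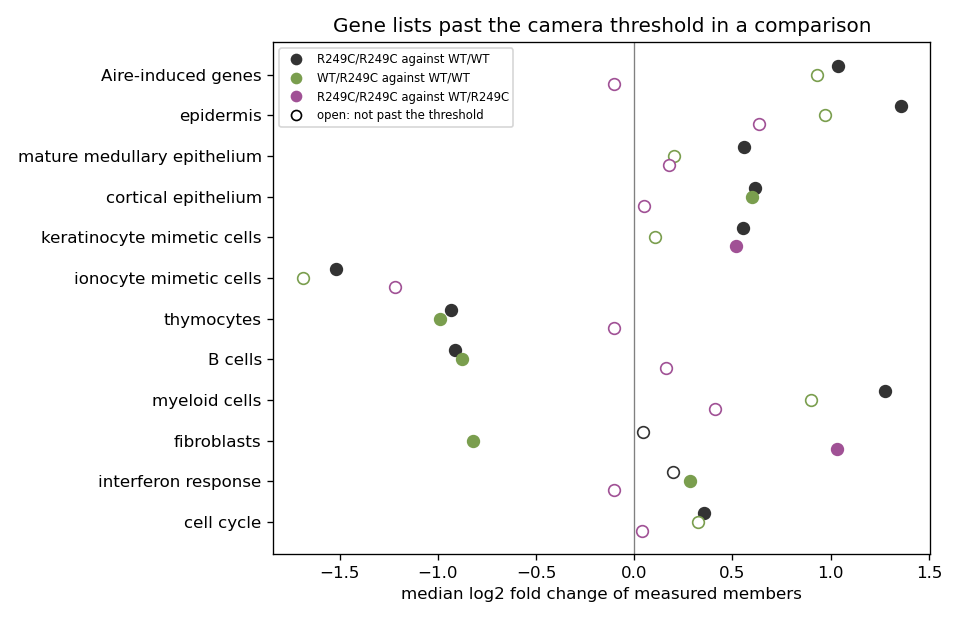
Median log2 fold change (x axis) of the measured members of each gene list (y axis) in the 3 comparisons, filled where the list passed camera at its preset correlation and open where it did not. B cell and thymocyte lists lie below 0 in both comparisons with WT/WT.

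The comparison of R249C/R249C with WT/R249C, in the 6 batch A libraries, asks what the other variant copy of Aire adds. The genes with the smallest p were mostly low transcripts found in all 3 libraries of a genotype and in none of the other. None passed by edgeR or limma voom. Amy1, the salivary amylase, was at 2.27 ± 1.46 CPM in R249C/R249C and 0 in WT/R249C (n = 3 and 3), at least 233-fold higher. Akap14, a kinase anchor of cilia, was at 1.81 ± 0.628 against 0, at least 195-fold higher, and Gria1, a glutamate receptor of neurons, at 0 against 2.05 ± 1.04, at least 195-fold lower. edgeR called 0 of 23695 genes, with 256 at an unadjusted p under 0.05, limma voom called 0, and DESeq2 called 33 (10 higher, 23 lower). Amy1, Akap14 and Acot6 are among the DESeq2 calls. Each of the 9 other splits of these 6 libraries, which mix the genotypes, gave more DESeq2 calls, from 34 to 367.

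Prrt2, a synaptic protein, was at 0.487 ± 0.0896 CPM against 0, at least 52.5-fold higher, the noncoding RNA Platr3 at 0.285 ± 0.0432 against 0, at least 30.3-fold higher, and AC125122.2 at 0.195 ± 0.108 against 0, at least 20.2-fold higher. The bitter taste receptor Tas2r109 was at 0 against 0.514 ± 0.206, at least 47.3-fold lower, and Myrfl, related to a myelin regulator, at 0 against 1.36 ± 0.466, at least 127-fold lower. Acot6, a peroxisomal thioesterase, was at 0.854 ± 0.387 against 12.2 ± 7.88 (log2 fold change -3.78), and AC124502.3 at 13.4 ± 4.64 against 56.3 ± 24.9 (-2.003). Outside this comparison, Amy1 was at 2.63 ± 2.29 CPM in WT/WT, near its value in R249C/R249C, and at 0.0722 in WT/R249C replicate 5. Prrt2 was at 0.435 ± 0.753 in WT/WT and 0.774 in WT/R249C replicate 4, and all 10 genes named for this comparison had counts in WT/WT.

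The fibroblast list was higher in R249C/R249C, with a median of 1.03 (adjusted p = 0.0151, and adjusted p = 0.967 with an estimated correlation). The collagen Col1a1 was at 147 ± 140 against 49.6 ± 32.1 CPM and the matrix protein Postn at 29.2 ± 33.0 against 7.91 ± 7.13. Much of this came from R249C/R249C replicate 2, with Col1a1 at 308 CPM against 74.5 and 57.5 in the other libraries of its genotype. Without that library the list had a median of 0.25 and did not pass (adjusted p = 0.238). The keratinocyte list had a median of 0.52 (adjusted p = 0.05, just under the threshold, and adjusted p = 0.967 with an estimated correlation). Grhl1 was at 67.3 ± 8.78 against 36.8 ± 6.45 and Pou2f1 at 43.1 ± 12.2 against 26.1 ± 13.0. The list of genes that need Aire did not pass (adjusted p = 0.377): its median was -0.10 while its mean was 0.12 and its test leaned upward, with Bpifb1 at 13.7 ± 10.7 against 5.01 ± 2.16 and the urinary protein Mup1 at 1.33 ± 0.878 against 0.665 ± 0.316. The mature medullary list did not pass (median 0.18, adjusted p = 0.156), with the costimulator Cd86 at 6.63 ± 2.95 against 1.63 ± 2.12. Of the 36 lists, 2 passed, against 1 without WT/R249C replicate 2, 1 without R249C/R249C replicate 3 and 6 without WT/R249C replicate 3, and 0 passed at an estimated correlation or by the fry PValue. By PValue.Mixed the salivary and lacrimal list passed (adjusted p = 0.00037), with a median of -0.03, a mean of 1.76 and an upward camera test that did not pass, and its member Amy1 was the 1 gene that passed when adjusted over the list alone, against 0 over all genes.

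Both mutant genotypes were set against the same WT/WT libraries, which ties their fold changes together. Across 26980 genes, which are not independent replicates, the 2 sets of log2 fold changes had a correlation of 0.713 and a covariance of 4.71, against 0.641 (SD 0.00789) and 3.34 (SD 0.0810) in 20 simulations of unchanged groups with shared controls. Among the 13490 genes above the median CPM, the correlation was 0.713 against 0.650, while the covariance of 0.504 lay below the simulated 0.941. With 0 calls in each, the overlap of calls was 0, as chance gives. The 3 WT/WT libraries cannot be split with 2 per part, so part of the excess over the simulations may come from the shared controls.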

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

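The tests on counts of 0, on batch, plasma cells and B cells for the immunoglobulin transcripts, and on mature medullary cells for Aire were chosen after the result was seen, while the splits that mix the genotypes were chosen before.

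Of 56 values tested in the 5 WT/R249C libraries, 9 had a library far from the others. The bound gives about 1 in 20 for normally distributed values. CPM values can be skewed and some were at 0, so an excess over chance is not shown. The 9 are not separate findings: Igkc is part of the immunoglobulin sum, and Prrt2 and Amy1 were at 0 in the other 4 libraries, so that any count stands apart. WT/R249C replicate 3 stood above the rest for summed immunoglobulin genes (671 CPM, nearest 203), Igkc (283, nearest 90.0) and Casp14 (15.6, nearest 4.37). Replicate 5 stood above the rest for Ensa (50.5, nearest 43.6), Bpifb1 (76.2, nearest 9.47), Cenpf (48.2, nearest 23.3), Mx1 (40.5, nearest 19.96) and Amy1 (0.0722, the others at 0). Replicate 4 alone held Prrt2, at 0.774 CPM. Replicates 3 and 5 were also the libraries with the lowest totals of this genotype, at 60560348 and 83119070 counts.

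Immunoglobulin transcripts were higher in WT/WT (5075 ± 2052 CPM, n = 3) than in WT/R249C (259 ± 232, n = 5; two-sided exact p = 0.0179, the smallest possible) and R249C/R249C (858 ± 345, n = 3; exact p = 0.1, the smallest possible), with Jchain, which joins antibody units, at 789 ± 258 in WT/WT against 75.5 ± 81.2 in the 8 mutant libraries. A batch difference is argued against, since within batch A the WT/WT library held 3.30 times the highest mutant library, and within batch B the ratio was 28.7. B cells in the WT/WT libraries are a candidate source: the score of 8 markers without immunoglobulin was higher there by 0.83 (2.87 ± 0.10 against 2.04 ± 0.48, exact p = 0.0242), with Cd79a at 8.52 ± 1.58 against 1.94 ± 1.87 CPM and Fcrla the other way at 2.52 ± 2.55 against 5.198 ± 5.08, while 0 of the markers are in another list and 7 had a mean above 1 CPM in mutant libraries too. Plasma cells are another: the score of 6 markers without Jchain was higher by 0.46, more than the SD of 0.36 among mutant libraries that had been set as the bound, yet with an exact p of 0.103, Mzb1 at 23.6 ± 14.5 against 2.48 ± 4.40 CPM, Derl3 and Pou2af1 lower in WT/WT, and the batch A WT/WT library (1.72) below the highest mutant library there (2.59). Depletion of CD45-positive cells and the sort would remove B cells, and the thymocyte score was also higher in WT/WT, by 0.71 (exact p = 0.0788), so a difference in sort purity and an effect of the genotype on B lineage cells in the thymus both stay open, the latter untested.

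DESeq2 called 408, 274 and 33 genes where edgeR called 0 in each comparison, with 865, 940 and 256 genes at an unadjusted p under 0.05. For R249C/R249C against WT/WT, 88.2% of the DESeq2 calls had at least 1 library at 0, against 40.2% of the genes it did not call, and 77.7% had a fitted log2 change beyond 10. Of the 9 other splits of these 6 libraries, which mix the genotypes, 6 gave DESeq2 counts at or above 408, and the highest was 629. Sparse transcripts that are on in some libraries and off in others may therefore make up most of these calls, whatever the grouping. The 48 calls with no library at 0 include Igkc, Ighg2b, Hnrnpdl and Hsd3b7, which edgeR did not call and for which an effect of the genotype stays open. For WT/R249C against WT/WT, 10 of the 19 other splits drawn gave DESeq2 counts at or above 274, and the highest was 1370. For R249C/R249C against WT/R249C, each of the 9 other splits gave more calls than the real 33, from 34 to 367.

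The genotype means of Aire ran from 490 to 603 CPM, and means vary less than single libraries. Within WT/R249C alone, Aire ran from 174 to 769 CPM in single libraries. It may follow the share of mature medullary cells in a library: log2 Aire and the score of the 18 other mature medullary markers had a Pearson r of 0.82 over 11 libraries (permutation p = 0.00211, adjusted 0.00844 over 4 relations) and a Spearman rho of 0.69 (permutation p = 0.022, adjusted 0.088). Without the 2 libraries farthest from the median r was 0.57, and within the 7 batch A libraries it was 0.85 (permutation p = 0.0225, adjusted 0.09; rho 0.86, permutation p = 0.0225, adjusted 0.09) and 0.61 without 2. With that score as a covariate, Aire in R249C/R249C against WT/WT was -0.32 on the log2 scale. The score itself was 7.22 ± 0.40 in WT/WT, 7.21 ± 0.46 in WT/R249C and 7.34 ± 0.37 in R249C/R249C, close to each other relative to this spread. The number of mature medullary cells was not measured, so an effect of the genotype on it was not tested.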

How the results depend on the processing

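Limma voom, the filter at a mean CPM of 10, the mature medullary covariate, leaving out both sparsest libraries and the immunoglobulin sum were chosen after the result was seen, and the other alternatives before. In all alternatives but DESeq2, edgeR and limma voom called 0 genes (24 for R249C/R249C against WT/WT, 25 for WT/R249C against WT/WT and 16 for R249C/R249C against WT/R249C, smallest adjusted p 0.476, 0.0678 and 0.821), and DESeq2 called 408, 274 and 33. With the replicate number as a replicate block, 0 genes passed in each. Of 9 such pairs 2 correlated above 0.1, and a block on library number was not fitted. Of 1569 values of 69 gene results without Aire, 1568 kept their direction, and 29 of them passed, all with DESeq2. The genes were picked by smallest p in these same libraries, so the kept direction is no independent support. Siglech in R249C/R249C against WT/WT ran from -0.67 without R249C/R249C replicate 3 to 8.84, since that library held all counts of its group. Camera kept its direction in all 377 values of 17 lists, 103 no longer passed, and 3 medians changed sign. The summed immunoglobulin genes kept their direction in 31 of 31 values, and for WT/R249C against WT/WT the log2 difference was -3.76 in batch A only and -4.17 with the contested libraries left out or counted as R249C/R249C (exact p = 0.1, the smallest possible). The lists were picked as passing in these same libraries, and the sum after it was seen in them. Their kept direction is no independent support either.

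The number of lists that passed for R249C/R249C against WT/WT (10) was 6 with the replicate block, 6 at a mean CPM of at least 10, 3 with no batch term, 4 with both contested libraries left out, 4 in batch A only and 2 (without WT/WT replicate 1) to 12 when each library was left out in turn, with 6 without R249C/R249C replicate 3. For WT/R249C against WT/WT (5) it was 10 with both sparsest libraries left out and 4 to 10 (without WT/R249C replicate 5) when each was left out, with 8 without WT/WT replicate 2. For R249C/R249C against WT/R249C (2) it was 5 with no filter on low counts, 5 with the replicate block, 6 with limma voom and 1 (without WT/R249C replicate 2 or R249C/R249C replicate 3) to 6 (without WT/R249C replicate 3). Aire changed sign with the mature medullary score as a covariate in all 3 comparisons, at -0.32, -0.060 and -0.28 on the log2 scale. For WT/R249C against WT/WT it was also -0.025 with limma voom, -0.14 in batch B only, and -0.14 (without WT/WT replicate 1) to 0.52 when each library was left out, and for R249C/R249C against WT/R249C -0.15 (without WT/R249C replicate 2) to 0.58, with -0.05 without R249C/R249C replicate 3. The difference in genes detected changed sign for R249C/R249C against WT/WT, at 1448 in batch A only, 105.5 at a minimum of 5 counts and -1040 to 1590 when each library was left out (1590, 358 and 117 without WT/WT replicate 3 and R249C/R249C replicates 3 and 2). For WT/R249C against WT/WT it was -178 with no thinning and -834 to 1857 when each was left out (-834, -773, -632, -309 and -281 without WT/R249C replicate 1, WT/WT replicates 2 and 1 and WT/R249C replicates 4 and 2). For R249C/R249C against WT/R249C it was 24.4 at a minimum of 5 counts and -1281 to 717 when each was left out (717, 207, 193 and 164 without WT/R249C replicate 1, R249C/R249C replicate 3 and WT/R249C replicates 4 and 2). The tissue-gene score changed sign in batch A only, at 0.28, 0.27 and 0.011 for the 3 comparisons in turn. When each library was left out it ran from -0.40 to 0.015 (without WT/WT replicate 3) and from -0.29 to 0.12, with 0.12, 0.04 and 0.00442 without WT/WT replicate 3 and WT/R249C replicates 2 and 3. For R249C/R249C against WT/R249C it was 0.011 with both contested libraries left out and 0.13 with them counted as R249C/R249C. Without the contested libraries the shared-change correlation was 0.876 (simulated 0.801). There and in batch A only, edgeR compared mutants with 1 WT/WT library, assumed to vary like other groups. For other changes the cause was not tested. Of simulated genes of at least 10 CPM changed 4-fold at most 25.4% were recovered, so many real changes of this size may have gone undetected.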

Other observations

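The tests on relations between library measures were chosen after the results were seen, and the splits of the libraries before.

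The other 3 relations of the family were weaker. Log2 Aire and the tissue-gene score had a Pearson r of 0.56 (permutation p = 0.0733, adjusted 0.124) and a Spearman rho of 0.39 (permutation p = 0.235, adjusted 0.417) over 11 libraries. Without the 2 farthest libraries r was 0.15, so the relation rested on those, and within batch A r was 0.59 (permutation p = 0.161). Log2 Aire and the genes detected had an r of 0.06 (permutation p = 0.855, adjusted 0.855) and a rho of 0.02 (permutation p = 0.968, adjusted 0.968), with 0.26 without 2 libraries and -0.21 within batch A. Summed immunoglobulin and the plasma cell score had an r of 0.53 (permutation p = 0.0928, adjusted 0.124) and a rho of 0.34 (permutation p = 0.313, adjusted 0.417), with 0.11 without 2 libraries and 0.10 within batch A.

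Other splits of the same libraries were fitted with edgeR. The real splits called 0 genes, which every split reaches, so the tallies of 56 of 56 splits for WT/R249C against WT/WT, 10 of 10 for R249C/R249C against WT/WT and 10 of 10 for R249C/R249C against WT/R249C say nothing about chance. The real counts at an unadjusted p under 0.05 were 940, 865 and 256 in that order, with 274, 408 and 33 genes by DESeq2 and 0 by limma voom. The highest other split of the 6 libraries called 0 genes in both comparisons with R249C/R249C, where 10 splits are also too few for a share under 0.05. For WT/R249C against WT/WT, 3 other splits called genes and the highest called 1450. That split set WT/WT replicate 1 and WT/R249C replicates 1 and 2 against the other 5 libraries, among which WT/R249C replicate 3 is the only one of batch A. With the batch term, the contrast of that split compares WT/R249C replicate 3 alone with the other side. The 1450 calls therefore rest on a single library, the one with the lowest total. Of the 4 splits that kept the 4 batch A libraries together, 1 called 108 genes, 1 called 12 and 2 called 0, and each set 1 batch B library apart from the other 3 (WT/R249C replicate 5 for 108 and WT/WT replicate 2 for 12). Within batch A alone and batch B alone, the real comparison called 0 genes.

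The thymocyte score was 3.47 ± 0.22 in WT/WT, 2.61 ± 0.62 in WT/R249C and 3.01 ± 0.52 in R249C/R249C, and the fibroblast score 5.50 ± 0.74, 4.30 ± 0.80 and 5.23 ± 0.61. The log2 immunoglobulin sum, chosen after the result was seen, was higher in R249C/R249C than in WT/R249C by 1.95 (exact p = 0.0536). This was 0.59 (exact p = 0.589) with the contested libraries counted as R249C/R249C, 2.37 (exact p = 0.0286) without WT/R249C replicate 3 and 2.34 (exact p = 0.0476) without R249C/R249C replicate 1. With the contested libraries counted so, R249C/R249C against WT/WT was -3.58 (exact p = 0.0357). Xist and the Y-linked gene Ddx3y were both present in every library.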
